A study of Mus musculus with 6 samples.

How the data were processed

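Small RNA reads from plasma extracellular vesicles of pregnant mice were analysed in 6 libraries, 3 from females on a normal diet and 3 from females on a high-fat diet. The starting point was 1 table with a line for each of 1030 miRNA entries and a column for each library. The values deposited by the authors are estimated counts of reads, not normalised. This was taken from the values themselves: most are whole numbers, the rest are simple fractions such as those left when a read that matches several miRNAs is shared equally among them, and the column totals differ between libraries. Every column name matched the title of 1 sample, and 0 other columns of per-sample values were present. The submitters' processing notes name Bowtie 0.12.2 and genome build mm8, with no role for either. The trimming, the miRNA reference, the counting rule and any filter on low counts are not given in the sources used here.

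The extraction protocol per the labels describes RNA from retina and an mRNA library kit, whereas the tissue and source labels name plasma extracellular vesicles and the table holds miRNAs. The conflict was left as it stands, the samples are described by their tissue label, and a list of retinal miRNAs was included among the lists below. The labels do not say whether the 3 samples of a diet came from separate animals or pools, so the p-values measure the spread between these samples, which may be partly technical. No library date or batch is given in the labels.

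Entries carry the mature miRNA name and, in many cases, a suffix. Suffixes such as those with L or R and a signed number were read as end offsets and those with ss as substitutions. This reading comes from their form alone. The table holds 1006 distinct names, of which 16 have more than 1 entry, and 123 entries have a substitution suffix. A further 97 entries, with names ending in p5 or p3, were read as hairpin fragments outside the named mature miRNAs. In the text, miRNAs are called by the mature name. Among entries with whole counts, a library held at most 4 values from 1 to 4 and 75 or more values from 5 to 8, so the table appears to have a minimum of about 5 counts per library. An entry at 0 is therefore treated as lying below 5 counts in that library, a floor that covers counting error only.

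Total counts per library ran from 1016178 to 3021732. The estimated counts were rounded to whole numbers. With R 4.3.3 and edgeR 4.0.16, entries were kept by filterByExpr with default settings, which left 485 entries holding 99.93% of all counts and set aside 545, of which 119 were at 0 in all libraries. Libraries were scaled with TMM factors, and the diets were compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, robust off) over all 6 libraries with no covariate. P-values were two-sided and adjusted by Benjamini-Hochberg over the 485 entries, and a miRNA was called at an adjusted p below 0.05. The common biological coefficient of variation was 38%. Log2 fold changes are high-fat diet over control, with their standard errors, and levels are normalised counts as CPM (edgeR's cpm with the TMM factors). Log2 CPM used a prior count of 2. Of the 485 entries, 125 held fractional counts, so part of their reads was shared with other names, and 18 had the same values as another entry, leaving 476 distinct sets of reads. Paralogous miRNAs such as the miR-29 and let-7 members are uncertain to that extent.

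The procedure was tested on simulated data made from the 485 entries of this comparison, with 200 changed and 10 rounds. It recovered 44% of the 2-fold changes and 85.5% of the 4-fold changes, 1.92% of its calls were false, and it made 0 calls on average when nothing was changed. A simulated shift of the let-7 list was found in all 10 rounds. Simulated entries varied independently, so this does not cover lists whose members vary together or share reads. Their dispersion followed the trend with level, not each miRNA's own, and the recovered shares hold for that setting.

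A set of 19 miRNA lists was fixed before the data were examined. They cover red cells, platelets, leukocytes, liver, muscle and heart, pancreas, neurons, retina, adipose tissue, lipid and glucose metabolism, the Sfmbt2, Dlk1-Dio3 and miR-322 genomic clusters, the let-7, miR-17, miR-200, miR-30 and miR-29 families, and inflammation. Each was tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, adjusted over the 19 lists. Camera with an estimated correlation and fry were run beside it. The share of all counts in each list, the number of entries detected and the library totals were compared with exact two-sided permutation tests, for which 3 libraries against 3 give a smallest p of 0.1.

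The miRNAs named in the text follow a rule set before the data were examined. It takes the 15 largest rises and the 15 largest falls among called miRNAs whose libraries do not overlap between diets, the 10 most abundant miRNAs, up to 4 called members of each list or otherwise its most abundant member, and 10 fixed names, of which miR-486a-5p was not analysed here. Hairpin positions come from GENCODE M21 on GRCm38, matched by miRNA name, and not from the table. The build of the processing notes is a different one. The annotation gave the places of hairpins, their grouping into clusters, neighbours and arm pairs, and GC content. No mature miRNA sequences were at hand, so GC content is that of the 5p or 3p side of the hairpin, split at its middle, and stands in for that of the mature arm. It was obtained for 429 of the 485 tested entries.

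Alternatives were other scalings (RLE factors, total counts, scaling without the red cell list), DESeq2 1.42.0, limma-voom, no filter and a filter of 50 counts in 3 libraries, other thresholds, each library left out in turn, and the replicate number as a block. Alternatives added after seeing the data were thinning all libraries to the smallest total, merging redundant names, scaling without the miR-29 list, other prior counts for log2 CPM and testing entries with whole counts alone. Pairs of libraries of 1 diet had a chi-square per degree of freedom from 53.1 to 819 against counting error, so no pair looked like 1 library deposited more than once. This does not tell separate animals from separate preparations of 1 pool.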

Results

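Extracellular vesicles, membrane-bound particles that cells release into blood with RNA inside, were collected from the plasma of pregnant mice. Females were kept on a high-fat or a normal diet for 8 weeks and then mated with males on normal diet. Each diet is represented by 3 miRNA libraries. Total counts were 1923011, 2696168 and 3021732 in control libraries 1, 2 and 3 and 1347541, 1464003 and 1016178 in high-fat libraries 1, 2 and 3. The first principal component of log2 CPM held 40.3% of the variance. On it, the control libraries lay between -11.82 and -8.02 and the high-fat libraries between 6.19 and 16.56. Every high-fat total lay below every control total, so this component cannot tell diet from depth.

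The first comparison asks which vesicle miRNAs differed between pregnant females on the high-fat diet and controls. The 3p arms of the miR-29 family, whose known targets include collagen and other extracellular matrix mRNAs, were higher on the high-fat diet. miR-29a-3p rose 14.4-fold, from 3748 ± 897 CPM in controls to 54110 ± 3470 CPM (SD, n = 3 each), miR-29c-3p rose 5.95-fold and miR-29b-3p rose 4.38-fold. miR-22-3p and miR-27a-3p, the latter a repressor of fat-cell differentiation, rose 2.63-fold and 2.67-fold. On the lower side were let-7 family members, miR-20a-5p and miR-17-5p of 1 proliferation-linked cluster, and miR-146b-5p and miR-155-5p, which are induced in inflammatory signalling.

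In all, 42 of the tested miRNA entries were called (edgeR, adjusted p below 0.05), 23 higher and 19 lower on the high-fat diet, and 34 of them changed at least 2-fold, 18 higher and 16 lower. They correspond to 41 distinct sets of reads, because the entry for let-7a-5p and a substituted entry for let-7c-5p hold the same counts. These sets are not fully separate: 23 of the 42 called entries held fractional counts, so part of their reads was shared with other names. Among all tested entries, 125 held such counts. In each of the 42, the 3 libraries of one diet all lay above the 3 of the other. The same held for 129 entries in all, or 26.6% of those tested, where chance gives 10%. The median log2 change over all tested entries was -0.08.

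Among the abundant miRNAs that rose, miR-29a-3p had a log2 change of 3.85 (SE 0.26, adjusted p = 0.000174). Its control libraries stood at 4295, 4235 and 2712 CPM and its high-fat libraries at 51300, 57990 and 53040 CPM. The mouse Mir29a hairpin lies on chromosome 6 at 31062660 to 31062747 (GRCm38) with no annotated host gene on its strand. miR-29c-3p went from 100.8 ± 24.4 to 599.4 ± 27.8 CPM (n = 3 each; log2 change 2.57, adjusted p = 0.00133). Its hairpin lies on chromosome 1 at 195037547 to 195037634 in an exon of the noncoding transcript A330023F24Rik. miR-29b-3p went from 186.2 ± 55.7 to 815 ± 121 CPM (log2 change 2.13, adjusted p = 0.00422). It has a hairpin in that same transcript, at 195037040 to 195037120, and another on chromosome 6 at 31063023 to 31063093 in an exon of Gm27019. All 3 names hold reads shared with other names.

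miR-27a-3p rose from 9087 ± 1080 to 24240 ± 3420 CPM (log2 change 1.42, adjusted p = 0.00752). Its hairpin on chromosome 8, 84208672 to 84208758, has no annotated host gene on its strand and lies beside those of miR-23a and miR-24-2. miR-24-3p rose 2.13-fold (log2 change 1.09, adjusted p = 0.0171), while miR-23a-3p had a log2 change of 0.21 (SE 0.20, adjusted p = 0.613). miR-22-3p, from an exon of Mir22hg on chromosome 11 at 75463716 to 75463810, rose from 16840 ± 5280 to 44220 ± 8600 CPM (log2 change 1.39, adjusted p = 0.029). miR-30e-5p rose 2.12-fold (adjusted p = 0.037) and miR-351-5p, of the X-linked miR-322 cluster, rose 1.96-fold (adjusted p = 0.0375).

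Among less abundant miRNAs, miR-141-3p, of the epithelial miR-200 family, rose from 113 ± 19 to 388.9 ± 9.03 CPM (log2 change 1.78, adjusted p = 0.00374). Its hairpin lies on chromosome 6 at 124717914 to 124717985 in an exon of Gm29008. miR-500-3p, from an intron of the chloride transporter gene Clcn5 on chromosome X at 7237683 to 7237774, rose 3.29-fold (adjusted p = 0.00374). miR-3535 rose from 2.63 ± 0.38 to 38.49 ± 6.51 CPM, or 14.2-fold, on 5 to 9 counts per control library. The hairpin fragment mir-5112-p5 had a log2 change of 4.06 with widely spread levels of 9.08 ± 8.37 and 148 ± 115 CPM (adjusted p = 0.0397). Its log2 change was 3.40 without high-fat library 3 and 5.22 without control library 1, and it was called in 9 of 15 alternative fits. Rises of 4.33-fold for miR-450a-2-3p, 3.18-fold for miR-134-5p and 3.02-fold for miR-291b-5p were measured at control levels of 11.69, 111.7 and 18.57 CPM. miR-3968, miR-879-5p and miR-615-3p, the last from an intron of Hoxc5, rose 2.36-fold, 2.31-fold and 2.14-fold.

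**Figure D1:**
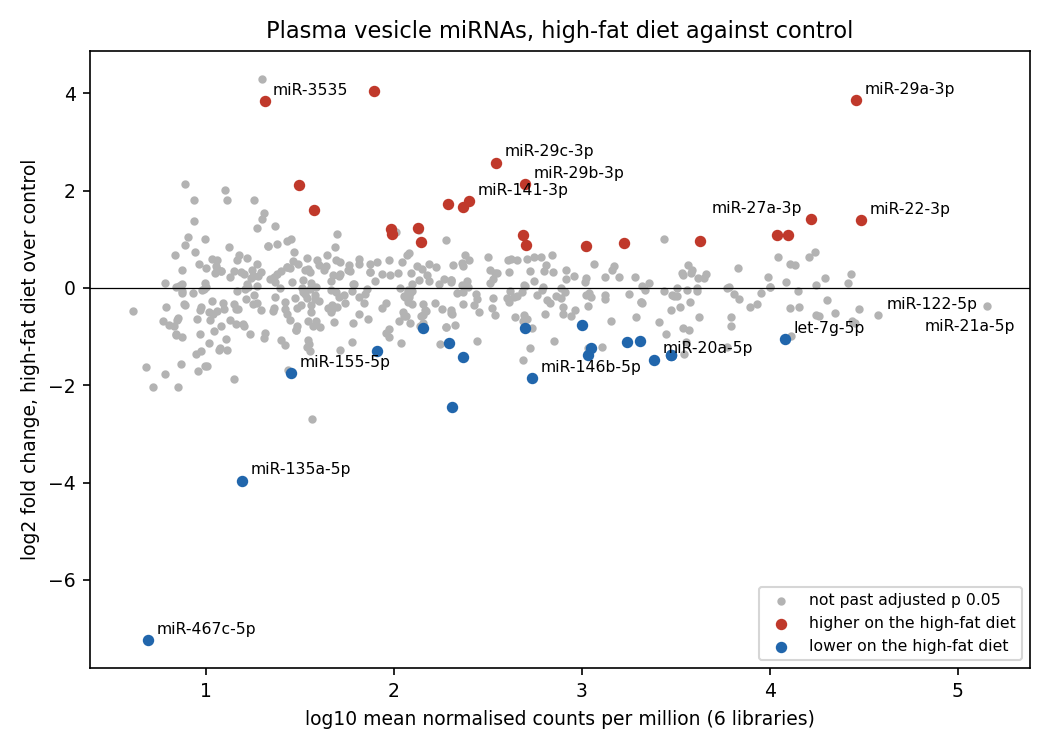
Log2 fold change (high-fat diet over control) of the tested miRNA entries against log10 of their mean normalised CPM over 6 libraries. Red points are the 23 entries called higher, blue points the 19 called lower and grey points those not called; miR-29a-3p stands apart among the abundant miRNAs, at a log2 change of 3.85, and miR-467c-5p, at 0 on the high-fat diet, is drawn at its fitted value, which is no measured fold.

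Of the miRNAs that fell, miR-20a-5p and miR-17-5p come from neighbouring hairpins on chromosome 14, at 115044157 to 115044263 and 115043671 to 115043754, in an exon of Mir17hg. miR-20a-5p fell from 3554 ± 404 to 1279 ± 130 CPM (log2 change -1.47, adjusted p = 0.00422) and miR-17-5p from 2772 ± 454 to 1295 ± 110 CPM (log2 change -1.10, adjusted p = 0.0196). miR-146b-5p, a negative regulator of inflammatory signalling from an intron of Mfsd13a on chromosome 19, 46342762 to 46342870, fell from 850.1 ± 278 to 235.9 ± 64.6 CPM (log2 change -1.85, adjusted p = 0.0163). miR-155-5p, from an exon of Mir155hg on chromosome 16, 84714140 to 84714204, fell from 44 ± 9.63 to 12.97 ± 3.68 CPM (log2 change -1.75, adjusted p = 0.0402). let-7a-5p, let-7c-5p and let-7g-5p had log2 changes of -1.39, -1.38 and -1.06. Within the miR-200 family, miR-200b-3p and miR-200c-3p fell to 0.464 and 0.566 of the control level, in the opposite direction to miR-141-3p.

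miR-135a-5p stood at 29.4 ± 10.7 CPM in controls and at 3, 2.5 and 2.5 shared counts in high-fat libraries 1, 2 and 3, below the apparent minimum of the table. Against a floor of 5 counts per library it was at least 7.45-fold lower, a bound that was not itself tested. The edgeR test, run on the rounded counts, gave miR-135a-5p an adjusted p of 0.0137, and it was called in 11 of 15 alternative fits. miR-467c-5p, from an intron of Sfmbt2 on chromosome 2 at 10473931 to 10474027, stood at 9.85 ± 3.08 CPM in controls and at 0 in all 3 high-fat libraries. Against the same floor it was at least 2.49-fold lower, again without a test of that bound. With the high-fat counts taken as 0, edgeR gave miR-467c-5p an adjusted p of 0.0397. It was called in 6 of the 11 alternative fits that gave it an adjusted p. The fragment mir-3470b-p3 fell 5.48-fold. miR-199b-5p, miR-877-5p, miR-184-3p and miR-450a-5p fell 2.68-fold, 2.46-fold, 2.34-fold and 2.18-fold, with adjusted p-values from 0.0304 to 0.0469.

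The most abundant miRNA, miR-21a-5p, stood at 161900 ± 8060 CPM in controls and 124800 ± 26600 CPM on the high-fat diet (log2 change -0.38, adjusted p = 0.401). Hepatocyte miR-122-5p had a log2 change of -0.57 (SE 0.62, adjusted p = 0.678), on control levels of 36360, 88040 and 11030 CPM. The log2 change was -0.68 for miR-192-5p, -0.44 for miR-143-3p, -0.71 for miR-191-5p, 0.29 for miR-27b-3p and 0.11 for miR-142a-5p, with adjusted p-values from 0.277 to 0.852. Red cell miR-451a, miR-486b-5p and miR-16-5p had log2 changes of -0.40, -0.51 and -0.39 (adjusted p from 0.405 to 0.615). Myeloid miR-223-3p and endothelial miR-126a-3p had log2 changes of -0.29 and -0.11 (adjusted p = 0.44 and 0.861). At this number of libraries the test recovered 44% of simulated 2-fold changes, so changes of such size could go uncalled.

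The number of calls was sensitive to the libraries used and the test: it lay between 8 (without high-fat library 2) and 24 (without control library 1) when 1 library was left out, was 70 with DESeq2, and was 2 of 362 among entries with whole counts alone. Of the 35 called entries named by the rule, 8 kept their call without each library in turn: the 3p arms of miR-29a, miR-29b and miR-29c, miR-3535, miR-141-3p, miR-500-3p, miR-27a-3p and miR-20a-5p. The calls of miR-155-5p, miR-184-3p, miR-200c-3p, miR-291b-5p and miR-450a-5p were lost without any 1 library, with adjusted p up to 0.173, and the other 22 were lost without at least 1. Calls lost were 14, 20 and 18 without control libraries 1, 2 and 3 and 19, 27 and 25 without high-fat libraries 1, 2 and 3. Every high-fat library was smaller than every control library, and no batch is given in the labels, so depth and any shared handling of a group went with diet.

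**Figure D2:**
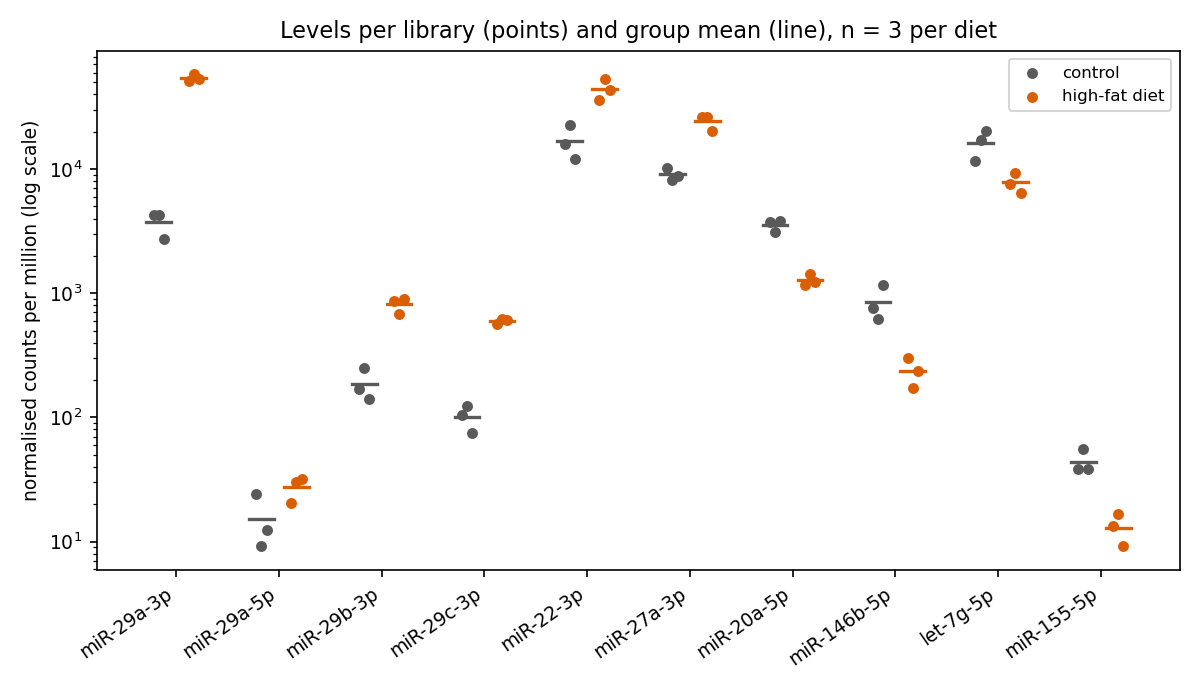
Normalised CPM on a log scale for 10 miRNAs in each library (points; grey control, orange high-fat diet, n = 3 each) with the group mean as a line. The high-fat libraries of miR-29a-3p lie from 51300 to 57990 CPM and its control libraries from 2712 to 4295 CPM, whereas the points of miR-29a-5p overlap between diets.

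The second comparison asks whether miRNAs of 1 family, genomic cluster or source tissue moved together. The miR-29 and let-7 families were the only lists of 19 past the camera test with its preset correlation, and neither passed with an estimated correlation (adjusted p = 0.386 and 0.928). In the miR-29 family, 3 of 5 tested members rose, 4 when adjusted over the list alone, and the median log2 change was 2.13 (camera adjusted p = 2.13e-06). The members not called over all miRNAs, named after their values were seen, were miR-29c-5p with a log2 change of 2.02 (adjusted p = 0.073) and miR-29a-5p with 0.86 (adjusted p = 0.424). The fry test of limma, which asks whether the members by themselves move on balance one way, gave an adjusted p of 0.00285 over the 19 lists. In the let-7 family, regulators of developmental timing and proliferation, 5 of 20 tested entries fell, 12 when adjusted over the list alone, 18 had negative changes and the median was -0.84 (camera adjusted p = 1.25e-05). Of the 5, let-7a-5p and a substituted let-7c-5p entry hold the same counts, and the 20 entries are 19 distinct sets of reads. DESeq2 called 11 let-7 entries and limma-voom 5, and fry gave the list an adjusted p of 0.0854. In the miR-29 family DESeq2 called 4 members, miR-29c-5p added, and limma-voom 3.

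Groups with called members but no call as a list went both ways or held few changes. In the miR-200 family of 7, miR-141-3p rose and miR-200b-3p and miR-200c-3p fell, with 1 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.875). In the miR-17 group of 18, miR-20a-5p and miR-17-5p fell, 2 also when adjusted over the list alone, and the median was -0.33 (adjusted p = 0.422). In the X-linked miR-322 cluster of 13, expressed in placenta and differentiating muscle, miR-450a-2-3p and miR-351-5p rose and miR-450a-5p fell. Adjusted over the list alone, 2 were higher and 3 lower (camera adjusted p = 0.875). Of those lower, miR-450b-3p and miR-450a-1-3p, named after their values were seen, hold the same counts. In the miR-30 family of 9, edgeR called miR-30e-5p, 1 also when adjusted over the list alone (adjusted p = 0.539), and DESeq2 called 3, miR-30e-5p, miR-30d-5p and miR-30a-5p. Of 8 miRNAs induced in inflammation, miR-155-5p and miR-146b-5p fell, 2 also when adjusted over the list alone (adjusted p = 0.539). In the adipose list of 15, miR-27a-3p rose and miR-146b-5p fell, with 2 higher and 1 lower when adjusted over the list alone (adjusted p = 0.539). DESeq2 called 4 adipose miRNAs, with miR-378a-3p and miR-222-3p added, and 3 in the miR-17 group, with miR-93-5p added. In the miR-200, miR-322 and inflammation lists it called as many as edgeR, and limma-voom called 1 inflammation miRNA. Names added by DESeq2 were chosen after their values were seen.

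Of the placental and embryonic clusters, the Sfmbt2 cluster had 20 members tested, of which miR-467c-5p fell and 0 passed when adjusted over the list alone or with DESeq2, with 2 at an unadjusted p below 0.05 (median -0.18, also with miR-467c-5p at its bound; adjusted p = 0.469). In the imprinted Dlk1-Dio3 cluster of 48, miR-134-5p rose, 1 also when adjusted over the list alone (adjusted p = 0.875), and DESeq2 called 2, with miR-494-3p added. Among source tissues, miR-24-3p was the 1 of 12 platelet miRNAs to rise (adjusted p = 0.875), miR-29b-3p rose and miR-155-5p fell among 10 leukocyte miRNAs (adjusted p = 0.875), and miR-184-3p fell among 7 retinal miRNAs (adjusted p = 0.788), with the same counts when adjusted over each list alone and with DESeq2. limma-voom called 1 leukocyte miRNA. The red cell (9 members), liver (6), muscle and heart (7), pancreas (4), neural (9) and lipid and glucose (11) lists had 0 members called in edgeR, also when adjusted over the list alone, and 0 with limma-voom. At an unadjusted p below 0.05 they held 1, 0, 2, 0, 0 and 2 members, and DESeq2 called as many: miR-144-5p, miR-1a-3p and miR-133a-5p, and miR-378a-3p and miR-26a-5p, names added after their values were seen. Their camera adjusted p-values were 0.539, 0.875, 0.788, 0.9, 0.875 and 0.875. The most abundant members of the muscle, pancreas and neural lists were miR-1a-3p with a log2 change of -0.98 (adjusted p = 0.127), miR-7a-5p with -0.29 (adjusted p = 0.544) and miR-128-3p with -0.12 (adjusted p = 0.861). Median, mean and camera direction differed in sign for the Dlk1-Dio3, miR-322, lipid and glucose, miR-200 and miR-30 lists.

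**Figure D3:**
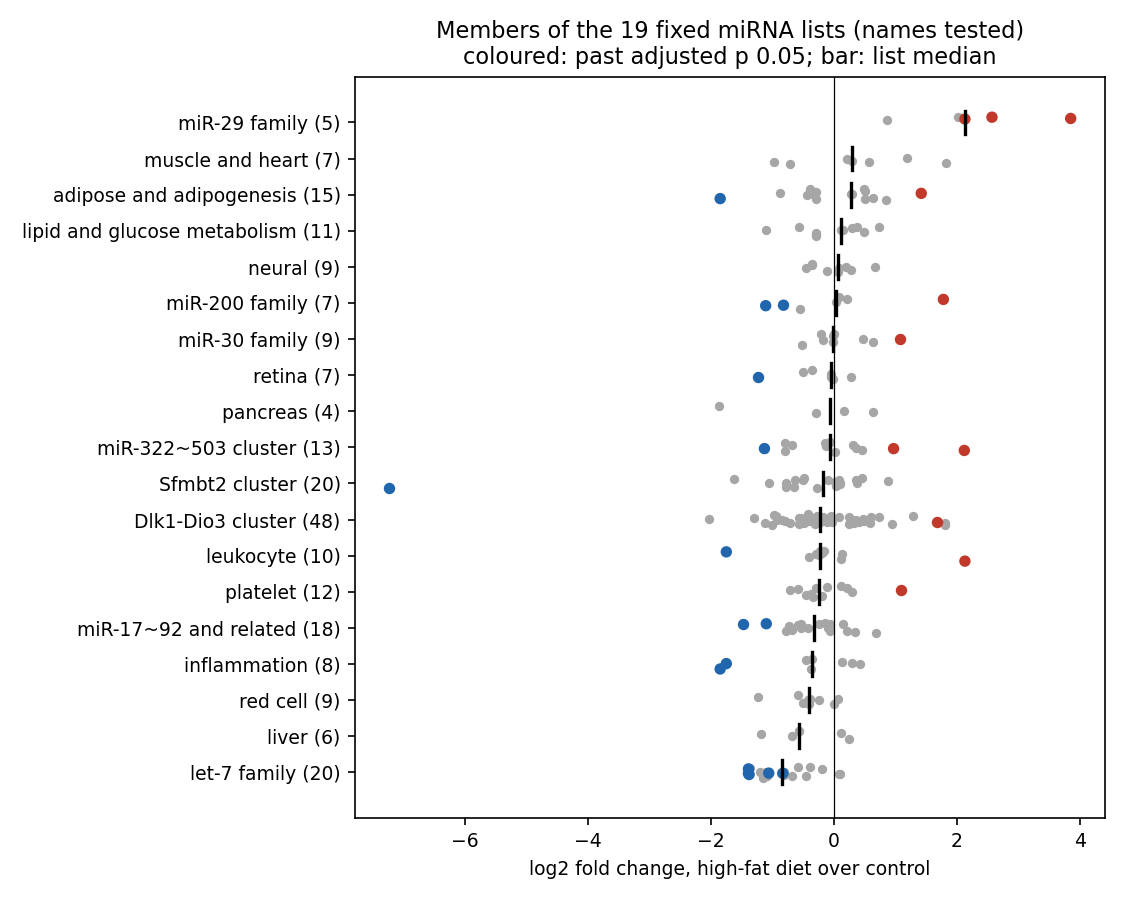
Log2 fold changes (high-fat diet over control) of the tested members of the 19 lists, 1 line per list with the number of tested members in brackets, ordered by list median (black bar). Coloured points are called members; all 5 miR-29 members lie above 0 and 18 of 20 let-7 entries lie below 0, and the leftmost point, miR-467c-5p of the Sfmbt2 cluster, is drawn at its fitted value.

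The third comparison asks how much of each library a group took. The miR-29 family made up 0.403 ± 0.106% of control counts and 5.61 ± 0.27% of high-fat counts (SD, n = 3 each). The let-7 family took 6.67 ± 1.67% and 3.77 ± 0.427%, the miR-30 family 4.2 ± 0.205% and 6.33 ± 0.468%, the miR-17 group 5.68 ± 1.36% and 4.36 ± 0.26%, and the miR-200 family 0.597 ± 0.063% and 0.465 ± 0.062%. In these 5 groups the libraries of the diets did not overlap, which gives an exact permutation p of 0.1, the smallest possible with 3 against 3 (0.38 adjusted over 19 lists). The shares of source tissues overlapped between diets: 10.4 ± 3.39% and 8.66 ± 1.46% for red cell miRNAs, 25 ± 3.03% and 21.2 ± 2.04% for platelet miRNAs, 9.82 ± 6.76% and 6.73 ± 0.959% for liver miRNAs, and 1.07 ± 0.248% and 0.978 ± 0.071% for retinal miRNAs. The exact permutation p-values of the other 14 lists, these among them, were 0.2 or more, and 0.57 or more after adjustment. The share held by inflammation miRNAs was 17.6 ± 1.83% and 14.3 ± 2.79%. Without miR-21a-5p, a member of both lists, the difference between diets went from -3.29 to 0.13 points for inflammation miRNAs and from -3.81 to -0.843 points for platelet miRNAs. Without single libraries, the difference was 0.567 points for liver miRNAs (control 2), 0.222 for red cell miRNAs and -0.55 for the miR-17 group (both control 3), 0.0424 for retinal miRNAs (control 1) and -1.7 for inflammation miRNAs (high-fat 1).

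The last comparison asks whether the libraries differed in complexity. Control libraries held 678 ± 29.3 miRNA entries above 0 and high-fat libraries 566.7 ± 27 (n = 3 each; exact permutation p = 0.1, the smallest possible). The 10 most abundant entries took 40.13 ± 3.85% and 40 ± 2.72% of the counts (exact permutation p = 1), and miR-21a-5p alone took 16.06 ± 1.83% and 12.59 ± 2.54% (exact permutation p = 0.1). At 10 or more counts, above the apparent minimum of 5 in the table, control libraries held 535.3 ± 22.9 entries and high-fat libraries 456.7 ± 22.2, a difference of -78.67 (exact permutation p = 0.1). Thinned to the smallest total, the diets held 442 ± 15.7 and 438.7 ± 5.03 such entries, a difference of -3.333 (exact permutation p = 0.8).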

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

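Chosen after seeing the data were thinning to the smallest total, merging redundant names, scaling without the miR-29 list, other prior counts for log2 CPM, the fit on entries with whole counts alone, and thinning joined to a limit of 10 counts. Every one of the 42 called entries kept its direction in every alternative that tested it. The libraries of these entries did not overlap between diets, so their direction could hardly have changed. miR-29a-3p, miR-29b-3p, miR-29c-3p, miR-141-3p, miR-500-3p, miR-20a-5p and miR-27a-3p were called in all 16 alternative fits of the scaling, test, filter, thinning, block and left-out library kinds, and miR-3535 in the 15 that tested it. Lowest were miR-200c-3p and miR-877-5p, in 5 of 16, and miR-155-5p and miR-184-3p, in 7 of 16. The fits with redundant names merged and on entries with whole counts alone are not among the 16. The latter tested 19 of the 42 called entries and called 2 of them.

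The 42 calls (23 higher, 19 lower) became 70 with DESeq2 (35 higher, 35 lower; 57 adjusted p-values were not given by the tool), and 65 at an adjusted p below 0.1. Calls of lower miRNAs were 29 with no filter, 34 at an adjusted p below 0.1 and 35 at an unadjusted p below 0.05 with a 2-fold change. Among the 362 entries with whole counts alone, edgeR called 2, of which 2 were higher and 0 lower, although 57 had an unadjusted p below 0.05 and the called entries' log2 changes moved by 0.014 on average. The cause was not tested. RLE factors gave 38 calls, total counts 34, limma-voom 41, scaling without the red cell list 36, a filter of 50 counts 48, thinning 50, merged names 41 and scaling without the miR-29 list 39. With 1 library left out, calls ranged from 8 to 24, higher from 7 to 15 and lower from 1 to 9, with fewer samples in the fit: 8 without high-fat library 2, 10 without high-fat 3, 17 without control 2, 18 without control 3, 19 without high-fat 1 and 24 without control 1.

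Deviations from the group mean correlated at -0.04, -0.10 and -0.05 within replicate numbers, and no library correlated best with its own number. With the replicate block, 11 entries were called (8 higher, 3 lower).

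Of the lists, the calls of let-7 and miR-29 were lost with an estimated correlation, at adjusted p = 0.928 and 0.386. In all other alternatives in which camera was run, let-7 ranged from 1.26e-06 to 0.000324 and miR-29 from 1.11e-06 to 0.000187. It was not run with DESeq2 or on entries with whole counts alone. With 1 library left out, the Dlk1-Dio3 list ranged from 0.0436 to 0.922 and the miR-17 group from 0.0268 to 0.995, both past the threshold without control library 2 alone. Uncalled abundant miRNAs changed sign with a library left out: log2 changes ranged from -0.68 to 0.05 for miR-143-3p, -1.01 to 0.32 for miR-122-5p, -1.04 to 0.30 for miR-192-5p, -0.08 to 0.30 for miR-142a-5p, -0.32 to 0.09 for miR-128-3p and -0.45 to 0.05 for miR-126a-3p. Without miR-21a-5p in the total, the difference in share was -0.843 points for platelet miRNAs, 5.95 for miR-29 and 0.13, reversed, for inflammation miRNAs. Without red cell miRNAs it was 5.7 for miR-29. The difference in detected entries, -111.3, was -78.67 at 10 or more counts and -3.333 when the libraries were also thinned, so at that limit depth accounts for nearly all of it. Thinning alone gave -105, which decides nothing, since the minimum of about 5 counts acted before thinning and thinned control libraries keep values below it. With 1 library left out, differences in share ranged from -6.1 to 0.567 points for liver, -2.8 to 0.222 for red cell, -5.54 to -2.65 for platelet, -4.32 to -1.7 for inflammation and -0.198 to 0.0424 for retinal miRNAs, from 5.08 to 5.35 for miR-29, -3.54 to -1.95 for let-7, 1.88 to 2.35 for miR-30, -1.83 to -0.55 for the miR-17 group and -0.168 to -0.0961 for miR-200. Planned pseudocounts for normalised values were not run on counts. Prior counts of 0.1 and 10 in log2 CPM, in place of 2, changed no call of the 19 lists.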

Other observations

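The tests of hairpin clusters and of neighbouring pairs, of depth for the miR-29 and let-7 patterns, of reads shared into miR-29a-3p, and of whole hairpin transcripts were chosen after the results were seen, and miRNAs named here outside the rule were chosen after their values were seen.

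Hairpins within 10000 bases of each other were grouped into 26 clusters with at least 3 tested entries from more than 1 hairpin. Entries whose name matched more than 1 hairpin were left out, the called miR-29b-3p and miR-24-3p among them. Neither cluster of miR-29 hairpins was therefore among the 26, and these were not tested. By fry of limma, adjusted over the 26, 3 clusters passed, each with a median log2 change above 0. Of the miR-23a, miR-27a and miR-24-2 cluster on chromosome 8 (84208518 to 84208921), 2 of 5 entries were called higher, miR-27a-3p and miR-24-2-5p with a log2 change of 0.86, and the median was 0.86 (adjusted p = 0.00956 by fry). The imprinted-region pair miR-296 and miR-298 on chromosome 2 (174267047 to 174267585) had all 3 entries above 0: miR-296-5p and miR-298-5p rose with log2 changes of 0.94 and 0.88, and miR-296-3p had 1.15 (adjusted p = 0.0775; cluster adjusted p = 0.0235 by fry). The Clcn5 cluster on chromosome X (7237683 to 7248497) had a median of 0.34, with miR-500-3p its 1 called member of 7 (adjusted p = 0.00956 by fry). Against the other miRNAs, camera gave these clusters adjusted p-values of 0.0525 or more, and 0.816 or more with an estimated correlation. The miR-290 cluster of early embryo and germ cells, which holds miR-291b-5p, had 6 of 8 entries above 0 and a median of 0.43 (adjusted p = 0.366 by fry).

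Some neighbouring hairpins differed. miR-141-3p and miR-200c-3p, from hairpins on chromosome 6 at 124717914 to 124717985 and 124718322 to 124718390, differed in log2 change by 2.61 (SE 0.29), and miR-27a-3p and miR-23a-3p by 1.20 (SE 0.29). The 838 pairs came from 32 clusters, and each cluster was given equal weight. The weighted mean absolute difference in log2 change was 0.71. Random pairings, made by shuffling log2 changes among entries of similar level, had a mean of 0.86, and 95% lay from 0.70 to 1.08. The observed value lay just inside that range. Both it and the random pairings held miR-467c-5p at its fitted log2 change of -7.23, which is no measured fold. Names matching more than 1 hairpin were left out. With so small a margin, the test does not decide whether neighbours change more alike than other miRNAs.

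The real grouping of the 6 libraries gave 42 calls and the highest of the other 9 groupings gave 0, so 1 of 10 was as large. With 10 groupings a share below 0.05 cannot be reached.

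The rise of the miR-29 3p arms was weighed first. Lower depth of the high-fat libraries is argued against by the unscaled counts of miR-29a-3p, which in the lowest high-fat library were 5.46 times those in the highest control library. Reads shared from miR-29b and miR-29c cannot make the rise of miR-29a-3p, since its log2 change after their counts were taken away was 3.96. Whether reads of miR-29a make part of the rise of miR-29b-3p and miR-29c-3p cannot be told apart from a rise of their own: they gained 629 and 499 CPM, and the difference of 130 CPM has an SE of 81.5. GC content of the hairpin side that holds the arm, a stand-in for that of the mature miRNA, is argued against as the whole cause by log2 changes of 4.15, 2.47 and 2.74 for miR-29a-3p, miR-29b-3p and miR-29c-3p after its trend was taken out. Across tested entries with a GC value, log2 change and this GC content had a Spearman rho of 0.25. Entries richer in GC thus tended to be higher on the high-fat diet. The cause of that trend was not tested, and the calls were not made again without it. For miR-29a-3p an effect of the diet is left as a hypothesis, found and tested on the same data. RNA from a cell type rich in miR-29 was not tested, for want of its profile.

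The lower let-7 family was weighed next, a pattern past camera with a preset correlation but not with an estimated one (adjusted p = 0.928). Less red cell RNA is argued against by the ratio of let-7 to red cell counts, which was 0.653, 0.702 and 0.599 in controls and 0.376, 0.502 and 0.444 on the high-fat diet, a log2 difference of -0.57 with a pooled SD of 0.17. After thinning, the let-7 median was -0.91. Thinning leaves the expected share of each entry unchanged, so this value could hardly have moved and does not decide whether depth plays a part. The GC content of the hairpin side as the whole cause is argued against by a median of -0.75 after the GC trend was taken out, which covered 19 of the 20 entries. A lower let-7 content on the high-fat diet is a candidate explanation, found and tested on the same data.

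The last pattern is that arms of 1 hairpin moved apart. Of 122 hairpins with both arms tested, 11 had arms whose log2 changes differed by more than 3 standard errors, where chance gives 2.1, which argues against more or less of the whole transcript as the only source. A shared part is not excluded: across the 122 hairpins the log2 changes of the arms had a Pearson r of 0.24 (permutation p = 0.008). The Spearman rho was lower, at 0.13, and 61 of the 122 had arms of the same sign, about as many as unrelated arms would give. The GC content of the hairpin side is argued against as the whole cause: after its trend was taken out, 9 hairpins passed the same limit, where chance gives 2.1. Only the counts of hairpins were compared, and the GC content of the mature arms was not measured. For miR-29a, the log2 ratio of 3p to 5p went from 8.03 ± 0.72 to 10.96 ± 0.30 (n = 3 each; exact permutation p = 0.1, the smallest possible), on 23 to 50 counts of the 5p arm per library. Arm-specific loading into vesicles or stability could produce this, and neither was tested. Arms whose name matched more than 1 hairpin were left out of the count of hairpins. The arms kept can still hold reads shared with other names, and the hairpins were not compared without such reads.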
